A study of Mus musculus with 34 samples.

How the data were processed

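Total RNA was measured by sequencing in 34 mouse livers, 1 library per liver. Per the labels, the mice were C57BL/6 animals homozygous for a tetracycline-responsive Cas9 (TetO-Cas9) and for the reverse tetracycline transactivator at the Rosa locus (Rosa-rtTA). They received an adeno-associated virus (AAV) carrying a guide RNA and were kept on a Western diet for 3 months. Per the labels' protocols, RNA was extracted with TRIzol and RNeasy columns, and libraries were made with a stranded total RNA kit for mammalian samples (SMARTer). Guides targeted Bcl6 (5 livers), Irs1 (5), Smyd2 (6), Srebf1 (5) or Tbx3 (7). Guides against GFP (sgGFP, 4 livers) and LacZ (sgLacZ, 2 livers), which the mouse genome does not carry, served as controls and were pooled as 1 control group of 6, since the series title names them together. Each liver is taken as a separate animal from the numbering of the labels. If any share an animal, p-values measure only the spread between these samples.

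The values deposited by the authors are FPKM (fragments per kilobase of transcript, scaled to the library's total), with a gene symbol and 34 columns of values, each of which matched the title or description of 1 sample. Per the submitters' processing notes, reads were counted with featureCounts 1.6.4, and the notes name the builds mm10 and GRCh38 without saying what each was used for. The aligner, the annotation and the strand setting of the counting are not given in the sources used here. Reads of a gene and of an antisense or overlapping neighbour therefore may not be separated. The near-identical members of the Cyp, Sult, Mup, Serpina1 and Slc22 families may share reads, and the split of signal within such a family is uncertain.

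The table held 35976 symbols, of which 9320 were at 0 in every library. By their decimal places, 11998 of the remaining 26656 symbols held 1 value per library and 14658 held sums of several values. Sums made up 6.2% of symbols with 1 RefSeq transcript and 94.2% of symbols with 2 or more, among the 90.3% of symbols that matched a RefSeq symbol. The deposited FPKM of most genes thus appear to be summed over transcripts, each with its own length. The columns summed to between 2790000 and 3090000 FPKM. Depth was estimated from the low values. Where whole reads are counted, the FPKM of a gene are whole multiples of the value of 1 read. Of 2412 low genes holding 1 value, 94.3% lay on such steps in the libraries where they were above 0 within a tolerance of 0.02 reads. Annotated transcript lengths then gave an implied depth of 2110000 to 3130000 counted reads per library, where 1215 annotated transcript lengths gave the same scale and at most 35 gave any other. No 2 libraries held identical values, and the highest Pearson correlation between any pair was 0.9835. Genes with few reads at this depth have wide errors, and a gene listed at 0 is below detection, not absent.

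The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), for the 19295 genes with an FPKM of 1 or more in at least 5 libraries. All 34 livers entered 1 fit with 6 levels (the 5 knockouts and the control), with an intensity trend in the moderated variances (eBayes, trend=TRUE). P-values are two-sided, adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. A log2 change is on the log2(FPKM + 1) scale, which understates the change of low genes. An F test over the same fit asked which genes differed among the 5 knockouts, and pairwise contrasts compared knockouts with each other. A fit with sgGFP and sgLacZ as separate levels compared the controls. Replicate values are given as mean FPKM ± SD.

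A total of 34 gene lists of 9 to 30 genes were fixed for liver metabolism, sex-biased and zonal liver expression, stress and immune responses, and the cell types a liver sample could hold. Each was tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists within a comparison. The test was repeated with an estimated correlation, and with fry, which asks whether a list's genes move 1 way on balance. A list needed 5 tested members. For each list the number of members past the threshold is given over all genes tested and adjusted over the list alone. The level of a list in a liver is the mean over its members of log2(FPKM + 1) minus the mean over the 34 livers.

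The groups, tests, lists and most alternatives were chosen before the data were examined. The genes to name were set by rule: the targeted genes, the 6 highest and the 6 lowest log2 changes past the threshold with every knockout liver on the same side of the control mean, and up to 3 members of each list past the threshold by smallest adjusted p (4 where the list was called). Unnamed loci were counted and not named, and some genes that the rule covers are not reported here. Where fewer than 5 genes passed, the 5 with the smallest p are given as values.

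Alternatives were a pseudocount of 0.1, no filter on low values, a filter at an FPKM of 5, median scaling, quantile normalization, a fit of the compared groups alone, sgGFP livers alone as control, the replicate number as a block, robust variances, array weights, and leaving out each liver in turn. Leaving out the 3 libraries lowest on the first principal component was added after the data were seen. The fit and the list test were tested on simulated data with 100 changed genes of each size per comparison. Among 19295 genes, a log2 change of 1 was recovered for 54% in the Bcl6, 45% in the Irs1, 59% in the Smyd2, 51% in the Srebf1 and 47% in the Tbx3 comparison, and a change of 2 for 83%, 83%, 85%, 89% and 89%. False calls made up 2 to 5.2% of all calls, and none of 40 unshifted lists was called in any comparison. Genes were simulated independently of each other, so this does not check the list test where the genes of a list are correlated. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.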

Results

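RNA from 34 mouse livers was sequenced after 3 months on a Western diet, a diet rich in fat and sugar. Each mouse could be induced to express Cas9 and had received an AAV with a guide RNA, so that Cas9 could cut 1 chosen gene in the liver. The design compares livers given guides against Bcl6 (5 livers), Irs1 (5), Smyd2 (6), Srebf1 (5) or Tbx3 (7) with 6 control livers, 4 given sgGFP and 2 given sgLacZ. The groups given guides against a mouse gene are called knockouts (KO) below, after their labels. The depth implied by the deposited FPKM was 2110000 to 3130000 counted reads per library, with a median of 2610000. By group it was 2300000 to 2610000 for sgGFP, 2650000 to 2660000 for sgLacZ, 2530000 to 2860000 for Bcl6 KO, 2470000 to 2730000 for Irs1 KO, 2430000 to 2670000 for Smyd2 KO, 2140000 to 2840000 for Srebf1 KO and 2110000 to 3130000 for Tbx3 KO. At this depth 19295 genes were tested, and the median SE of a log2 change was 0.24 to 0.26 across the 5 comparisons. Values below are mean FPKM ± SD, knockout against control, and changes are on the log2(FPKM + 1) scale, on which the side of a liver relative to the control mean was also judged.

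The mRNA of each targeted gene was examined first, in every liver. Coordinates are of GRCm38 with the GENCODE M21 annotation, in which all 5 genes are protein-coding. The positions of the guides within them are not given in the sources used here. Bcl6, a transcriptional repressor (chromosome 16, 23965052 to 23988852, minus strand), stood at 64.3 ± 20.98 against 67.1 ± 31.7 FPKM (limma adjusted p = 0.9798), with 46.7 to 100.1 in the knockout livers and 27.1 to 104.1 in the controls. Irs1, an adaptor of the insulin receptor (chromosome 1, 82233101 to 82291416, minus strand), stood at 29.8 ± 3.92 against 23.5 ± 2.92 FPKM (limma adjusted p = 0.165), with 25.4 to 35.8 against 20.2 to 27.6. Smyd2, a lysine methyltransferase (chromosome 1, 189880492 to 189922363, minus strand), stood at 93.5 ± 22.8 against 115 ± 26.1 FPKM (limma adjusted p = 0.742), with 61.7 to 121.4 against 81.6 to 147.4. Tbx3, a T-box transcription factor (chromosome 5, 119670669 to 119684724, plus strand), stood at 134 ± 59.5 against 98.3 ± 39.5 FPKM (limma adjusted p = 0.441), with 80.1 to 248.5 against 45.9 to 147.1. In these 4 comparisons the targeted mRNA did not pass the test in either direction, except that under quantile normalization Irs1 passed as higher in Irs1 KO (log2 change 0.54). A cut gene can still be transcribed, so mRNA level does not check these 4 labels.

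Srebf1, which encodes the lipogenic transcription factor SREBP-1 (chromosome 11, 60199089 to 60222581, minus strand), was the exception in part. Its mRNA was at 498.8 to 631.7 FPKM in 4 livers labelled Srebf1 KO and at 1908 in the library labelled Srebf1 KO replicate 1, against 1095 to 2177 in the controls. Over all 5 livers the values were 816 ± 612 against 1499 ± 447 FPKM (log2 change -1.06, SE 0.26, limma adjusted p = 0.0611). Without the library labelled Srebf1 KO replicate 1 the log2 change was -1.42 (SE 0.21, limma adjusted p = 0.000318, lower in 4 of 4 livers). The Srebf1 level of that library goes against its label.

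**Figure D1:**
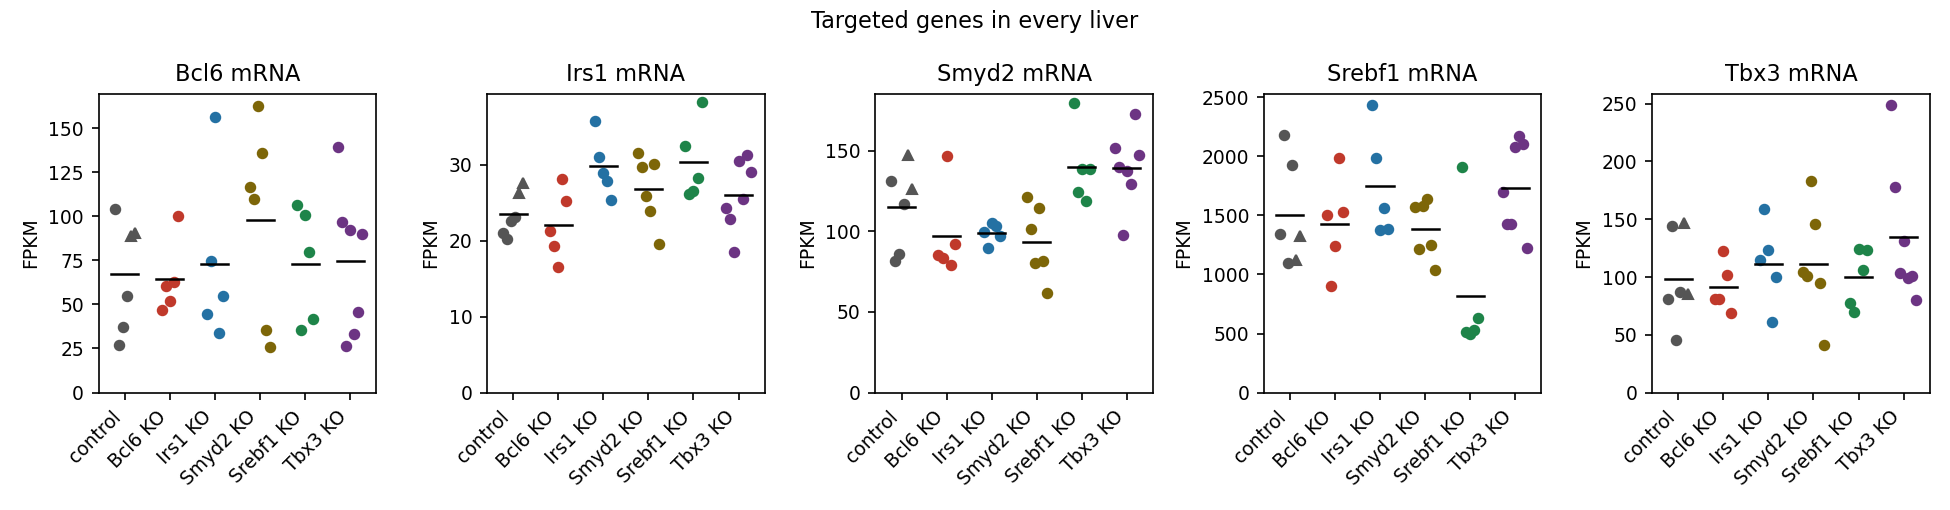
FPKM of the 5 targeted genes (vertical axes, 1 panel per gene) in each liver of the 6 groups (horizontal axes), with circles for livers, triangles for sgLacZ controls and a black line at each group mean. Srebf1 lay at 498.8 to 631.7 FPKM in 4 Srebf1 KO livers and at 1908 in the library labelled replicate 1, while the other targeted mRNAs overlapped the controls in their own knockout.

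Bcl6 KO livers carried high levels of transcripts that are typical of female mouse liver. Of 28 female-biased genes measured, 19 rose and 1 fell (camera adjusted p = 4.29e-56). The steroid hydroxylases Cyp2c69 and Cyp2c40 stood at 434 ± 148 against 0.804 ± 0.704 FPKM and 594 ± 148 against 2.84 ± 3.68 FPKM (limma adjusted p = 7.02e-23 and 3.76e-16). Prlr, the prolactin receptor, stood at 8471 ± 2749 against 327 ± 191 FPKM (log2 change 4.799, SE 0.36, limma adjusted p = 8.64e-12). Of 27 male-biased genes 13 fell and none rose, but this list call ended with an estimated correlation (camera adjusted p = 0.0837). The called genes named for Bcl6 KO lay on the stated side of the control mean in 5 of 5 knockout livers. For the highest and lowest changes the naming rule required this.

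Among the largest increases were those of A1bg, Cyp3a16, Cyp2c69, Sult2a1 and Cyp2c40. A1bg, a plasma glycoprotein, was listed at 0 in all control livers and stood at 691 ± 209.7 FPKM in the knockout (SE of the log2 change 0.17, limma adjusted p = 1.84e-29). Sult2a1, a sulfotransferase of steroids and bile acids, and Cyp3a41b were likewise listed at 0 in the controls and stood at 262 ± 134 and 154 ± 24.5 FPKM. Cyp3a16 stood at 681 ± 254 against 1.19 ± 1.198 FPKM (limma adjusted p = 1.16e-19). Adjusted over the list alone, 21 female-biased genes were higher and 1 lower, and the list call held with an estimated correlation (adjusted p = 5.47e-08). The level of this list was 3.25 to 3.81 in the Bcl6 KO livers and -0.53 to 0.38 in the controls. The counts of 19 higher members were the same under median scaling and quantile normalization. Genes of the sex chromosomes did not follow, with 0 of 9 past the threshold.

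The largest decreases were in the male-biased Cyp4a12a (6.74 ± 9.07 against 91.9 ± 58.2 FPKM, limma adjusted p = 6.29e-06), the pheromone-binding urinary protein Mup20 (1344 ± 1619 against 12040 ± 5818 FPKM), Cyp2d9 (39.9 ± 56.3 against 231 ± 142 FPKM, log2 change -3.18, SE 0.56), Cidea, Tinag and the small nucleolar RNA Snord69. Snord69 was listed at 0 in all 5 knockout livers, against 24.1 ± 18.6 FPKM (limma adjusted p = 0.0160, and 0.0511 with sgGFP livers alone as control). Tinag, a basement membrane protein, was at 0.443 ± 0.991 against 14.02 ± 9.49 FPKM (limma adjusted p = 0.0202), and its call ended without Bcl6 KO replicate 1 or 4 (adjusted p up to 0.0552). C8a, a complement component, fell by 1.86 on the log2 scale (SE 0.24). For the male-biased list, 15 members were lower adjusted over the list alone. Its camera adjusted p with the preset correlation was 8.07e-13.

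**Figure D2:**
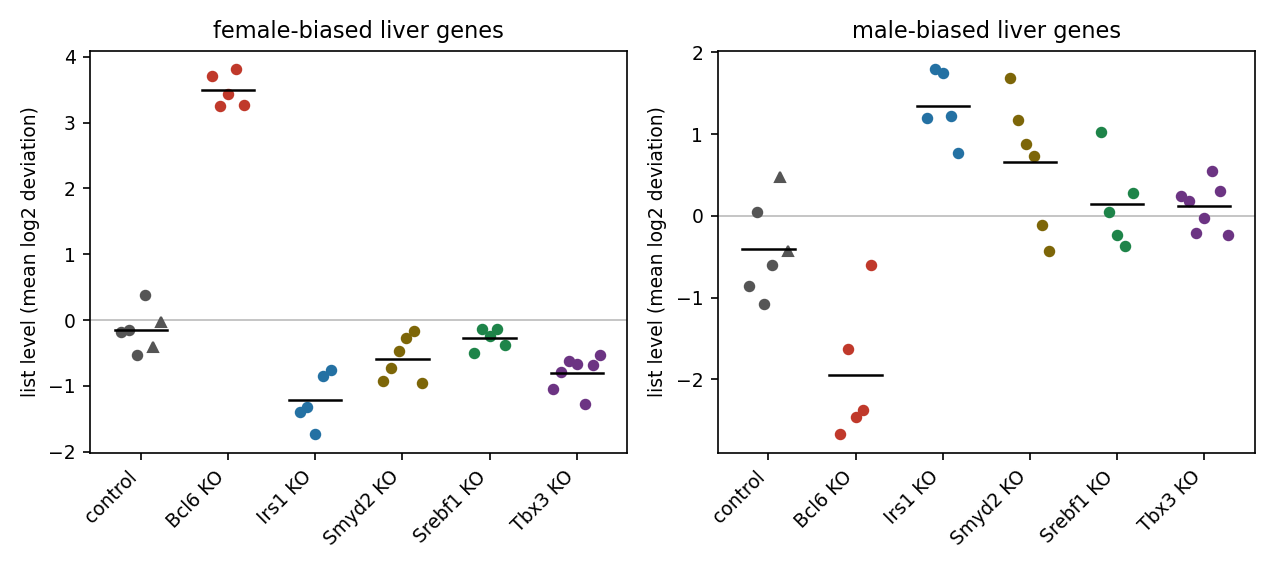
Level of the female-biased and the male-biased list (mean log2 deviation from the mean of the 34 livers, vertical axes) in each liver of the 6 groups, with circles for livers, triangles for sgLacZ controls, a black line at each group mean and a grey line at 0. Bcl6 KO livers lay at 3.25 to 3.81 for the female-biased list against -0.53 to 0.38 in the controls, and Irs1 KO livers at 0.77 to 1.796 for the male-biased list against -1.08 to 0.48.

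Genes of hepatocyte function rose as well. Of 26 hepatocyte genes 11 rose and 1 fell, 13 and 2 adjusted over the list alone (camera adjusted p = 8.07e-13, and 0.0258 with an estimated correlation). Albumin (Alb) stood at 131500 ± 26540 against 45810 ± 6557 FPKM (log2 change 1.51, SE 0.14, limma adjusted p = 1.84e-09) and transferrin (Trf) at 19330 ± 2157 against 9165 ± 757 FPKM. Of 23 acute phase genes 6 rose, 10 adjusted over the list alone, among them Itih4 (20840 ± 4841 against 4507 ± 884 FPKM, log2 change 2.198, SE 0.18) and ceruloplasmin, Cp (25890 ± 4986 against 10190 ± 698 FPKM, log2 change 1.33, SE 0.12). The camera adjusted p of that list was 1.99e-08, and adjusted p = 0.138 with an estimated correlation. In the growth hormone list 4 of 13 members rose, by either adjustment, with Ghr, the growth hormone receptor, at 4087 ± 1230 against 1153 ± 211 FPKM (camera adjusted p = 0.000220, and 0.00908 with an estimated correlation). Among 28 genes of xenobiotic metabolism 9 rose, 11 adjusted over the list alone, with the aldo-keto reductase Akr1b7 at 14.7 ± 5.19 against 0.939 ± 0.603 FPKM (camera adjusted p = 4.11e-08, and 0.0301 with an estimated correlation).

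Genes of lipid droplets fell in 10 of 22 cases and rose in none. Adjusted over the list alone 2 were higher and 13 lower (camera adjusted p = 9.84e-07, and 0.0437 with an estimated correlation). The droplet proteins Cidec and Cidea stood at 94.7 ± 70.1 against 554 ± 134 FPKM and 4.89 ± 10.4 against 38.1 ± 22.9 FPKM (limma adjusted p = 2.06e-05 and 0.00289). In Cidea the library Bcl6 KO replicate 5 was at 23.4 FPKM and the other 4 at 0 to 0.988. Of 29 apolipoprotein and lipoprotein genes 6 rose and 3 fell, 8 and 3 adjusted over the list alone. Lcat, which esterifies plasma cholesterol, rose by 0.95 (SE 0.12) on the log2 scale and Apom by 1.34 (SE 0.21), while hepatic lipase, Lipc, fell by 0.98 (SE 0.16). The camera adjusted p of this list was 0.000188, and adjusted p = 0.0614 with an estimated correlation. Of 23 periportal genes 5 rose and 2 fell, 8 and 2 adjusted over the list alone (camera adjusted p = 0.000251, and 0.144 with an estimated correlation).

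Other lists had members past the threshold in Bcl6 KO without a list call, here for fatty acid synthesis, bile acids, fatty acid oxidation and fetal liver (camera adjusted p = 0.813, 0.804, 0.114 and 0.193). Of 20 fatty acid synthesis genes 4 rose and 1 fell, 4 and 4 adjusted over the list alone, with a median log2 change of -0.43. The desaturase Fads1 stood at 2723 ± 579 against 985 ± 96.7 FPKM, and Aacs, an acetoacetyl-CoA synthetase, fell (38.99 ± 17.3 against 96.7 ± 28.7 FPKM). Of 22 bile acid genes 4 rose and 3 fell, 4 and 8 adjusted over the list alone. The 5-beta-reductase Akr1d1 rose (2326 ± 581 against 893 ± 316 FPKM), while the phospholipid transporter Abcb4 (1341 ± 286 against 2306 ± 246 FPKM) and the efflux pump Abcc3 (346 ± 140.4 against 858 ± 104 FPKM) fell. Of 27 genes of fatty acid oxidation 1 rose, Cyp4a31 (94.1 ± 26.9 against 29.7 ± 12.4 FPKM), and 5 fell, 2 and 5 adjusted over the list alone. The peroxisomal genes Acaa1b and Pex11a fell by 0.92 (SE 0.19) and 1.26 (SE 0.27) on the log2 scale. Of 18 genes of fetal liver 3 rose, and 3 were higher and 1 lower adjusted over the list alone, with a mean log2 change of 0.18 and a median of -0.26. Among them were the imprinted Peg3 (425 ± 211 against 33.6 ± 7.09 FPKM) and Igdcc4 (54.4 ± 42.9 against 2.75 ± 3.24 FPKM).

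Markers of other liver cells moved in different directions in Bcl6 KO. Of 19 endothelial genes 5 rose, 6 adjusted over the list alone, with the sinusoidal lectin Clec4g at 107 ± 17.1 against 60.8 ± 12.04 FPKM (camera adjusted p = 4.05e-05, and 0.0837 with an estimated correlation). Of 28 stellate cell genes 2 fell, 13 adjusted over the list alone. Loxl2, a collagen cross-linking enzyme, was at 35.2 ± 7.45 against 81.96 ± 32.8 FPKM (limma adjusted p = 0.0153, and 0.0564 without Bcl6 KO replicate 1). The stellate list had a camera adjusted p of 4.32e-06, and adjusted p = 0.494 with an estimated correlation. Of 15 cholangiocyte genes 1 fell, 2 adjusted over the list alone (camera adjusted p = 0.000461, and 0.464 with an estimated correlation).

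In all, limma called 1185 of 19295 genes in Bcl6 KO, 570 higher and 615 lower, of which 304 and 193 changed at least 2-fold. Higher calls made up 48.1% here, 64.2% under median scaling and 59.3% under quantile normalization. The count was 750 in a fit of Bcl6 KO and control alone, and 743 without Bcl6 KO replicate 4.

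Counts of list members in Bcl6 KO moved by over 1.5 times without single livers. The 19 higher female-biased genes were 11 to 14 of 23 left by the filter without 1 Bcl6 KO liver (moving without replicates 1, 2 or 4). Without 1 control they numbered 17 to 19 of 28. Without Bcl6 KO replicate 1 or sgLacZ replicate 2 the higher growth hormone genes numbered 2. The 2 lower stellate cell genes became 0 without Bcl6 KO replicate 1 and ranged up to 5, moving also without Bcl6 KO replicates 3 or 4 or sgGFP replicate 4. The lower cholangiocyte gene, Sox9, lost its call without Bcl6 KO replicates 1 or 4 or sgGFP replicates 1 or 3 and in the fit of the 2 groups. Lower lipid droplet genes numbered 4 to 11 (moving without Bcl6 KO replicates 1, 2 or 4 or sgLacZ replicate 2), and higher endothelial genes 3 without Bcl6 KO replicates 1, 2, 3 or 4, sgGFP replicate 2 or sgLacZ replicate 2. Higher xenobiotic genes numbered 5 without Bcl6 KO replicate 4 or sgGFP replicate 3. The higher fatty acid synthesis genes and the lower apolipoprotein genes numbered 2 and 1 without Bcl6 KO replicate 4. Among fatty acid oxidation genes 2 to 5 were lower, among bile acid genes 2 to 6, and among periportal genes 1 to 3. The counts of higher hepatocyte, acute phase and periportal genes and of lower male-biased genes stayed within 1.5 times.

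Irs1 KO livers expressed less of the genes of lipid storage and of connective tissue cells. They expressed more male-biased and periportal genes, lists also called higher in Smyd2, Srebf1 and Tbx3 KO. Lipid droplet genes fell in 11 of 22 cases, with Cidec at 61.7 ± 29.7 against 554 ± 134 FPKM (log2 change -3.22, SE 0.43, limma adjusted p = 1.77e-05) and the fatty acid transporter Cd36 at 1050 ± 372 against 2968 ± 381 FPKM. Of 27 male-biased genes 14 rose, led by the steroid dehydrogenase Hsd3b5 at 168 ± 58.9 against 1.22 ± 1.53 FPKM (limma adjusted p = 5.50e-05). The collagen genes Col1a1 and Col3a1 fell from 37.5 ± 22.9 to 4.92 ± 2.99 and from 96.4 ± 53.2 to 16.7 ± 6.25 FPKM. With an estimated correlation the calls of the lipid droplet, male-biased and periportal lists held, and that of the stellate cell list ended (camera adjusted p = 0.174). The called genes named for Irs1 KO lay on the stated side of the control mean in 5 of 5 knockout livers. For the highest and lowest changes this was required by the naming rule.

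Steatosis genes were lower in 12 of 22 cases adjusted over the list alone (camera adjusted p = 1.26e-10, and 0.00955 with an estimated correlation). Apoa4, an apolipoprotein of intestine and liver, stood at 1203 ± 403 against 3322 ± 886 FPKM and the glycerol channel Aqp7 at 0.149 ± 0.104 against 36.9 ± 35.5 FPKM (limma adjusted p = 2.98e-05 and 0.000373). Of 20 genes of fatty acid synthesis 8 fell, 10 adjusted over the list alone, with the desaturase Scd1 at 34960 ± 3561 against 67360 ± 15640 FPKM and the carboxylase Acacb at 339.8 ± 54.2 against 674 ± 176 FPKM. That list had a camera adjusted p of 0.000178, and adjusted p = 0.281 with an estimated correlation. Of 27 genes of fatty acid oxidation 9 fell and 1 rose, 14 and 1 adjusted over the list alone, among them the thioesterase Acot2 (17.2 ± 6.05 against 69.5 ± 24.2 FPKM, log2 change -1.94, SE 0.303) and Vnn1 (162 ± 45.7 against 384 ± 80.4 FPKM, log2 change -1.26, SE 0.21). Its camera adjusted p was 6.72e-05, and adjusted p = 0.281 with an estimated correlation. Cholesterol synthesis genes fell in 4 of 25 cases and rose in 1, 7 and 1 adjusted over the list alone, with Hmgcs1 at 178 ± 11.6 against 409 ± 96.3 FPKM. This list call (camera adjusted p = 0.0111, and 0.533 with an estimated correlation) ended with sgGFP livers alone as control (0.110) and without sgGFP replicate 2 or sgLacZ replicate 2 (up to 0.0676).

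Among 19 genes of insulin signalling and gluconeogenesis 4 rose and 1 fell, 6 and 1 adjusted over the list alone (camera adjusted p = 0.00110, and 0.00955 with an estimated correlation). The gluconeogenic enzyme Pck1 rose (5623 ± 800.1 against 3398 ± 828 FPKM, limma adjusted p = 0.0115, and 0.0571 under quantile normalization). Irs2, the other main insulin receptor substrate of liver, stood at 14.2 ± 3.53 against 8.37 ± 3.11 FPKM (limma adjusted p = 0.0254). The Irs2 call ended without Irs1 KO replicate 1 or 2, sgGFP replicate 2 or sgLacZ replicate 2 (adjusted p up to 0.0853), in the fit of the 2 groups and with sgGFP livers alone as control (up to 0.113).

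Of the male-biased genes 19 were higher and 1 lower adjusted over the list alone (camera adjusted p = 2.05e-19, and 0.0313 with an estimated correlation). The largest increases were in Hsd3b5, the urinary protein genes Mup7, Mup1, Mup16 and Mup11, and the microRNA gene Mir1942 (24.2 ± 9.74 against 0.996 ± 2.44 FPKM). Mup7 stood at 6312 ± 4818 against 287 ± 568 FPKM and Mup1 at 1338 ± 908 against 42.6 ± 45.5 FPKM, Mup16 at 526 ± 504 against 33.98 ± 47.8 FPKM and Mup11 at 228 ± 205 against 14.2 ± 23.9 FPKM, and these near-identical genes may share reads. Serpina1e, a serine protease inhibitor, and the complement component C8b stood at 888 ± 710 against 46.9 ± 21.9 FPKM and 1046 ± 254 against 180.5 ± 41.9 FPKM. Female-biased genes fell in 8 of 28 cases, 11 adjusted over the list alone, with Cyp2a4 at 3.27 ± 1.88 against 49.2 ± 19.98 FPKM. That list had a camera adjusted p of 9.76e-06, and adjusted p = 0.0689 with an estimated correlation. Of 13 growth hormone genes 1 rose, the receptor Egfr (872 ± 318 against 255 ± 74.7 FPKM), and 1 fell. The list call (camera adjusted p = 0.0243, and 0.0885 with an estimated correlation) ended under quantile normalization (0.131) and without Irs1 KO replicate 5 (0.0561).

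Of 28 stellate cell genes 18 fell and none rose, 22 adjusted over the list alone, with periostin, Postn, at 81.5 ± 14.6 against 210.3 ± 43.2 FPKM (limma adjusted p = 0.000361). The camera adjusted p was 3.75e-12, and adjusted p = 0.174 with an estimated correlation. Of 26 macrophage genes 13 fell, and 1 was higher and 21 lower adjusted over the list alone. The receptor Csf1r stood at 154 ± 40.9 against 304 ± 76.1 FPKM, Gpnmb at 0.791 ± 0.613 against 23.1 ± 18.1 FPKM and the elastase Mmp12 at 8.95 ± 4.96 against 76.5 ± 35.8 FPKM. This list had a camera adjusted p of 5.05e-07, and adjusted p = 0.258 with an estimated correlation. The stellate list lay at -0.91 to -0.49 in the Irs1 KO livers and 0.11 to 1.38 in the controls, with the highest control levels in sgGFP replicates 1 and 3. Endothelial genes fell in 2 of 19 cases without a list call (camera adjusted p = 0.563). Of 15 cholangiocyte genes 3 fell, 6 adjusted over the list alone, among them osteopontin, Spp1 (300.1 ± 116 against 1377 ± 879.5 FPKM; camera adjusted p = 0.00167, and 0.343 with an estimated correlation).

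**Figure D3:**
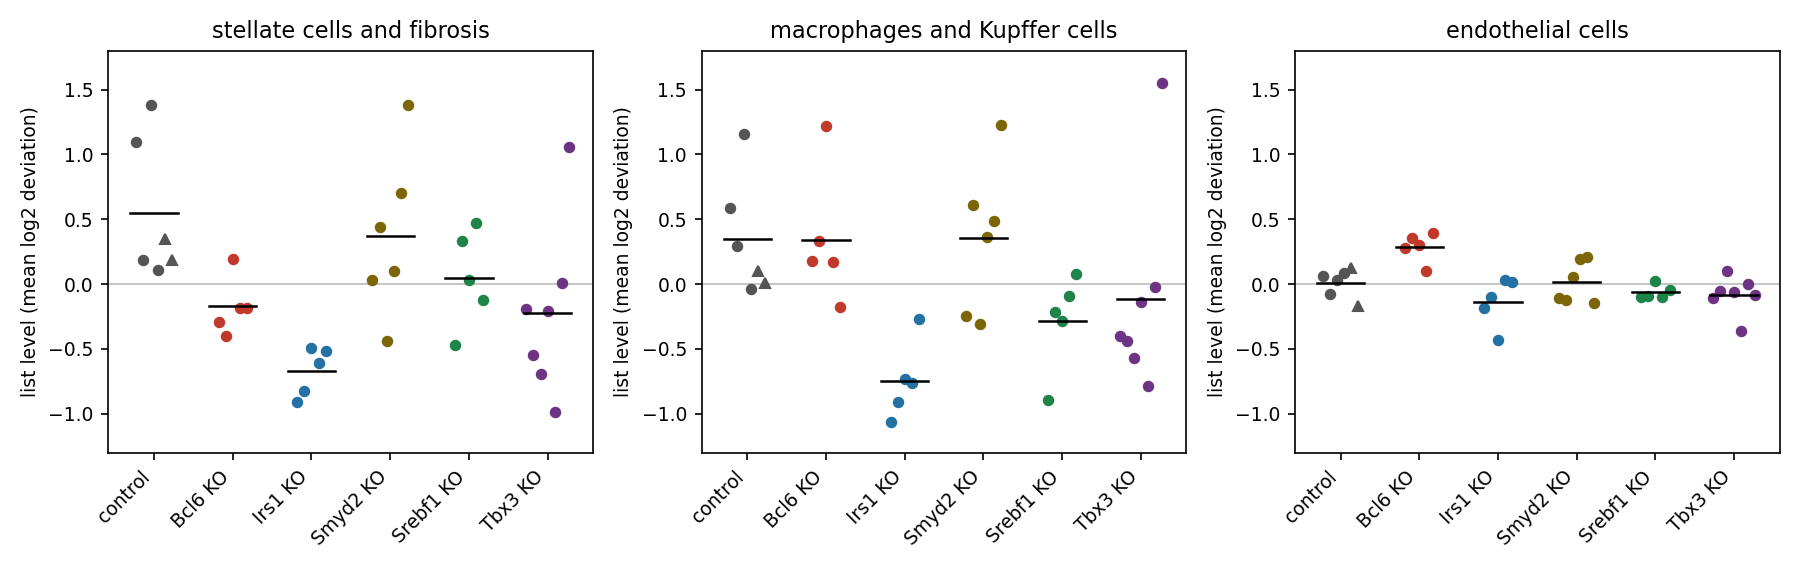
Level of the stellate cell, macrophage and endothelial lists (mean log2 deviation from the mean of the 34 livers, vertical axes) in each liver of the 6 groups, with circles for livers, triangles for sgLacZ controls, a black line at each group mean and a grey line at 0. Irs1 KO livers lay at -0.91 to -0.49 for stellate cells, -1.06 to -0.27 for macrophages and -0.43 to 0.03 for endothelial cells, against 0.11 to 1.38, -0.04 to 1.15 and -0.17 to 0.12 in the controls.

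Genes of hepatocyte function rose in Irs1 KO in 11 of 26 cases, 12 adjusted over the list alone (camera adjusted p = 5.17e-14, and 0.0121 with an estimated correlation). The urea cycle enzyme Cps1 stood at 5435 ± 652 against 2554 ± 602 FPKM and the nuclear receptor Hnf4a at 2006 ± 79.7 against 1418 ± 129 FPKM (limma adjusted p = 0.000116 and 9.64e-05). Of 23 periportal genes 11 rose, and 15 were higher and 1 lower adjusted over the list alone (camera adjusted p = 7.33e-13, and 0.00955 with an estimated correlation). Hal, which degrades histidine, and the immunoglobulin receptor Pigr stood at 474 ± 27.3 against 167 ± 71.7 FPKM and 1346 ± 128 against 635 ± 104 FPKM. Of 27 pericentral genes 6 rose and 1 fell, 8 and 1 adjusted over the list alone, with Cyp1a2 at 561 ± 84.5 against 179 ± 68.1 FPKM (camera adjusted p = 5.62e-05, and 0.174 with an estimated correlation). Bile acid genes rose in 7 of 22 cases and fell in 2, 10 and 2 adjusted over the list alone. The oxysterol hydroxylase Cyp7b1 and the transporter Slco1a1 stood at 272 ± 149 against 59.99 ± 36.9 FPKM and 572 ± 89.9 against 85.4 ± 86.6 FPKM (camera adjusted p of the list 2.11e-06, and 0.0531 with an estimated correlation). Both genes are also in the male-biased list.

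Stress and immune lists also moved in Irs1 KO. Of 25 NRF2 targets 14 fell, 21 adjusted over the list alone, with the glutathione transferases Gstm3 and Gstm2 at 31.8 ± 12.2 against 257 ± 70.2 FPKM and 80.4 ± 20.4 against 224 ± 79.4 FPKM (camera adjusted p = 1.13e-09, and 0.0689 with an estimated correlation). Among 25 genes of the unfolded protein response 8 rose and 1 fell, 13 and 2 adjusted over the list alone, with the chaperone Hyou1 at 700.4 ± 67.5 against 345 ± 86.4 FPKM and the stress factor Atf3 at 2.19 ± 0.799 against 12.9 ± 8.02 FPKM (camera adjusted p = 4.42e-07, and 0.0885 with an estimated correlation). Cell cycle genes fell in 11 of 30 cases, 16 adjusted over the list alone, with Hmmr at 5.69 ± 1.99 against 30.1 ± 16.1 FPKM (camera adjusted p = 4.42e-07, and 0.245 with an estimated correlation). Interferon genes fell in 9 of 28 cases, 12 adjusted over the list alone, with Ifit2 at 22.4 ± 4.47 against 70.1 ± 21.1 FPKM (camera adjusted p = 6.72e-05, and 0.318 with an estimated correlation). Of 24 p53 targets 6 fell, 9 adjusted over the list alone, with the cell cycle inhibitor Cdkn1a at 6.79 ± 2.76 against 39.5 ± 22.2 FPKM (camera adjusted p = 0.00108, and 0.285 with an estimated correlation). Fetal liver genes fell in 6 of 18 cases, 7 adjusted over the list alone, with the imprinted RNA H19 at 2.22 ± 2.18 against 35.5 ± 24.8 FPKM (camera adjusted p = 0.00208, and 0.154 with an estimated correlation). Cytokine genes fell in 5 of 22 cases, 8 adjusted over the list alone (camera adjusted p = 0.00471, and 0.323 with an estimated correlation). The largest decreases included also Slc22a27, an organic anion transporter (4.14 ± 4.66 against 49.98 ± 11.04 FPKM), Sprr1a (0.562 ± 0.768 against 19.4 ± 7.59 FPKM) and Arhgap22 (7.27 ± 6.71 against 77.3 ± 32.5 FPKM).

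The apolipoprotein and circadian lists were called in Irs1 KO with limits. Of 29 apolipoprotein genes 10 rose and 5 fell, 12 and 6 adjusted over the list alone (camera adjusted p = 0.000108, 0.0531 with an estimated correlation, and 0.0757 under quantile normalization). The circadian list was called toward higher values (mean log2 change 0.13), although the 1 of its 21 members past the threshold fell (camera adjusted p = 0.0293, 0.233 with an estimated correlation, up to 0.152 without Irs1 KO replicate 1 or 2 or sgGFP replicate 3). This call also ended under median scaling, quantile normalization and array weights, and in a fit, chosen after the data were seen, without sgGFP replicate 3, Tbx3 KO replicate 7 and Smyd2 KO replicate 6 (up to 0.193).

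In all, limma called 2094 genes in Irs1 KO, 625 higher and 1469 lower, of which 195 and 685 changed at least 2-fold. The median log2 change of all genes was -0.12 here and 0.005 after median scaling. Higher calls made up 29.8% as deposited, 51.9% under median scaling (1011 higher and 937 lower) and 49.3% under quantile normalization. Without single livers some list counts moved by over 1.5 times: to 5 for fatty acid synthesis (without Irs1 KO replicate 3 or sgLacZ replicate 2), 4 higher bile acid and 7 periportal genes (Irs1 KO replicate 1 or sgGFP replicate 1), 3 higher pericentral genes (Irs1 KO replicate 1), 2 higher insulin genes (Irs1 KO replicate 1 or sgGFP replicate 2), 8 macrophage genes (sgGFP replicate 3), 5 cell cycle genes and 1 endothelial gene (Irs1 KO replicate 3 or sgGFP replicate 3), 3 cytokine genes (Irs1 KO replicates 1 or 3 or sgGFP replicates 1 or 3), 5 cholangiocyte genes (sgGFP replicate 4) and 5 higher genes of the unfolded protein response (Irs1 KO replicates 2, 3 or 4 or sgGFP replicates 1 or 4). The single circadian gene lost its call without 6 of 11 livers.

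Livers labelled Srebf1 KO expressed more of the enzymes of cholesterol synthesis and less of several enzymes of fatty acid synthesis. Of 25 cholesterol synthesis and uptake genes 9 rose, 15 adjusted over the list alone (camera adjusted p = 1.39e-24, and 0.0440 with an estimated correlation). Idi1, the isopentenyl diphosphate isomerase, stood at 25.8 ± 13.3 against 3.82 ± 1.97 FPKM (log2 change 2.37, SE 0.34, limma adjusted p = 0.000432), and the sterol demethylase Cyp51 at 167 ± 88.6 against 35.9 ± 11.03 FPKM. Acacb, the acetyl-CoA carboxylase of mitochondria, fell from 674 ± 176 to 169.5 ± 58.7 FPKM (log2 change -1.999, SE 0.22, limma adjusted p = 2.67e-06). The called genes named for Srebf1 KO lay on the stated side of the control mean of log2 values in 5 of 5 knockout livers, which the naming rule required of the highest and lowest changes.

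The highest changes were in Idi1, squalene epoxidase (Sqle, 73.2 ± 38.5 against 13.7 ± 4.37 FPKM), Cyp51, Msmo1 (371 ± 177 against 84.6 ± 10.8 FPKM, limma adjusted p = 3.45e-05), Hsd17b6, a hydroxysteroid dehydrogenase (536 ± 131 against 186 ± 100.5 FPKM), and the HMG-CoA synthase Hmgcs1 (1362 ± 701 against 409 ± 96.3 FPKM). In the library labelled Srebf1 KO replicate 1 these enzymes were lower than in the other 4, at 6.02 FPKM against 23.1 to 42.8 for Idi1, 13.1 against 57.5 to 106.6 for Sqle, 38.2 against 114.9 to 254 for Cyp51, 126 against 271 to 583 for Msmo1 and 404 against 859 to 2080 for Hmgcs1. Controls ranged over 0.968 to 7.11, 6.60 to 18.4, 22.4 to 54.6, 67.2 to 94.0 and 308 to 577. The Sqle and Hmgcs1 values of that library were below the control means in FPKM, though above them on the log2 scale. The count of higher cholesterol genes was 3 without Srebf1 KO replicate 4 and also moved by over 1.5 times without replicate 2. Without the library labelled replicate 1, 10 cholesterol genes rose (camera adjusted p = 3.72e-42, and 0.000940 with an estimated correlation). The log2 change of Idi1 was then 2.799 (SE 0.30).

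**Figure D4:**
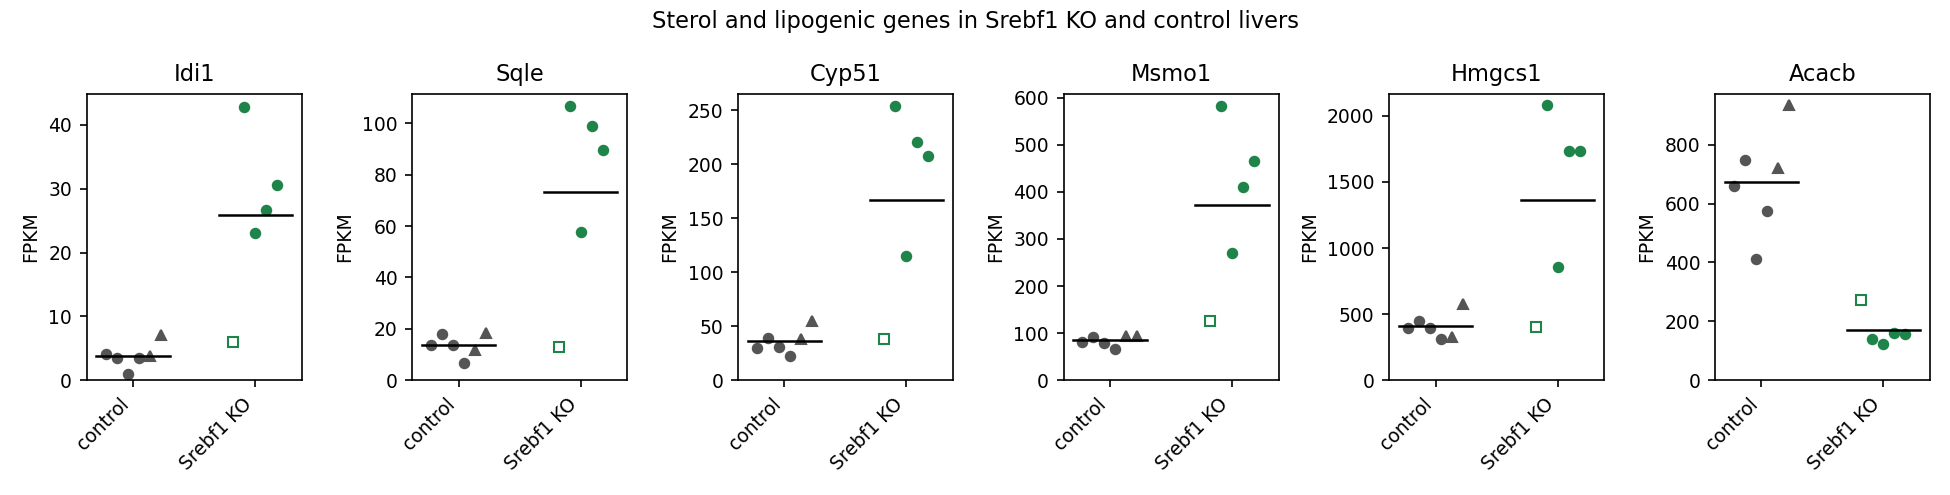
FPKM of Idi1, Sqle, Cyp51, Msmo1, Hmgcs1 and Acacb (vertical axes) in each control and Srebf1 KO liver, with circles for livers, triangles for sgLacZ controls, an open square for the library labelled Srebf1 KO replicate 1 and a black line at each mean. In the other 4 Srebf1 KO livers Idi1 lay at 23.1 to 42.8 FPKM and Acacb at 123 to 159, against 0.968 to 7.11 and 410 to 933 in the controls.

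Of 20 fatty acid synthesis genes 3 fell, 11 adjusted over the list alone: Acacb, Fads1 (552 ± 105 against 985 ± 96.7 FPKM, log2 change -0.85, SE 0.14) and Fads2 (852 ± 209 against 1375 ± 127 FPKM), the latter both desaturases of polyunsaturated fatty acids. The camera adjusted p was 1.15e-09, and adjusted p = 0.0947 with an estimated correlation. The lowest changes were in H19 (2.61 ± 2.62 against 35.5 ± 24.8 FPKM), the lipase Pnpla5 (1.71 ± 1.23 against 12.8 ± 6.57 FPKM), Siglecf (0.0877 ± 0.196 against 6.33 ± 5.99 FPKM), the fatty acid binding protein Fabp5 (16.1 ± 7.53 against 80.1 ± 32.8 FPKM), Cyp1b1 (1.25 ± 0.759 against 8.55 ± 4.13 FPKM) and Slit2 (1.03 ± 0.593 against 8.82 ± 7.14 FPKM). Acot2 fell as well (22.3 ± 5.56 against 69.5 ± 24.2 FPKM), and the carbonic anhydrase Car3, a gene of the adipocyte list that hepatocytes also express, rose (6215 ± 496 against 2608 ± 949.7 FPKM).

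Hepatocyte genes rose in 1 of 26 cases, the protease inhibitor Serpina1c (1094 ± 282 against 506 ± 144 FPKM), and in 4 adjusted over the list alone (camera adjusted p = 4.68e-11, and 0.0454 with an estimated correlation). Periportal genes rose in 2 of 23 cases, 10 adjusted over the list alone, with Pigr at 1092 ± 148 against 635 ± 104 FPKM (camera adjusted p = 6.90e-09, and 0.0440 with an estimated correlation). Without the library labelled Srebf1 KO replicate 1 these adjusted p with an estimated correlation were 0.106 and 0.1045. Apolipoprotein genes rose in 1 of 29 cases, Apoc1 (10100 ± 1298 against 5609 ± 2135 FPKM), and 7 were higher and 2 lower adjusted over the list alone (camera adjusted p = 3.97e-05, and 0.0521 with an estimated correlation). The 6 adipocyte genes had 1 past the threshold, Car3, and 2 adjusted over the list alone (camera adjusted p = 0.00686, and 0.0557 with an estimated correlation).

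Other lists were called in Srebf1 KO with at most 1 member past the threshold over all genes. Toward higher values these were the unfolded protein response (9 of 25 adjusted over the list alone, camera adjusted p = 2.82e-08, and 0.0947 with an estimated correlation), bile acid genes (4.80e-05, and 0.0947), pericentral genes (3.51e-06, and 0.127), male-biased genes (0.000239, and 0.392) and xenobiotic metabolism (0.00137, and 0.212), with the estimated-correlation value given last for each. Toward lower values they were macrophages (1.69e-05, and 0.392), stellate cells (3.97e-05, and 0.425), cholangiocytes (0.000230, and 0.378), cell cycle (0.00206, and 0.487) and fetal liver genes (0.0135, and 0.2701), all camera adjusted p in the same order. The calls of 5 further lists (insulin signalling, cytokines, neutrophils, circadian clock and oxidative phosphorylation; camera adjusted p from 0.000997 to 0.0475) ended under an alternative or without 1 of Srebf1 KO replicates 1, 2, 4 or 5, any sgGFP replicate or sgLacZ replicate 1 (up to 0.219). None of these 5 held with an estimated correlation (camera adjusted p from 0.0947 to 0.488).

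In all, limma called 73 genes in Srebf1 KO, 38 higher and 35 lower, of which 20 and 19 changed at least 2-fold. Of the named genes Acacb and Fads1 kept their call in every alternative and without any 1 liver, and Idi1, Cyp51 and Msmo1 lost theirs only in the fit of the 2 groups (limma adjusted p = 0.0751, 0.110 and 0.0631). Sqle lost its call without Srebf1 KO replicate 2 or 4 and Hmgcs1 without replicate 4 (limma adjusted p up to 0.0577 for each), and both also in the fit of the 2 groups (0.125 and 0.140). Every other named gene lost its call without sgGFP replicate 1, most of them also without another liver (up to 0.0548 for Serpina1c and 0.159 for Slit2), and all of these but H19 also in the fit of the 2 groups. The count of genes was 10 in the fit of the 2 groups and 152 with sgGFP livers alone as control. It was 14 without sgGFP replicate 1, 30 without sgGFP replicate 3, 110 without sgGFP replicate 4, and 39, 25, 20 and 41 without Srebf1 KO replicates 2, 3, 4 and 5. Without the library labelled Srebf1 KO replicate 1 it was 53, of which 46 were among the 73.

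Tbx3 KO livers expressed more periportal genes. Of 23 periportal genes measured 13 rose and none fell, 18 adjusted over the list alone (camera adjusted p = 1.13e-23, and 0.000191 with an estimated correlation). The glutaminase Gls2, which feeds ammonia to the urea cycle, stood at 726 ± 144 against 316 ± 85.6 FPKM (log2 change 1.22, SE 0.17, limma adjusted p = 3.45e-05), Cps1 at 5458 ± 405 against 2554 ± 602 FPKM and arginase, Arg1, at 2378 ± 220.2 against 1497 ± 256 FPKM. Sult1e1, which sulfates estrogens, stood at 2392 ± 1042 against 104 ± 157 FPKM (limma adjusted p = 3.43e-05), and Igfbp2, a binding protein of insulin-like growth factors, at 618 ± 100.3 against 132 ± 44.1 FPKM. The called genes named for Tbx3 KO lay on the stated side of the control mean of log2 values in 7 of 7 knockout livers.

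The other highest changes were in AW549542 (117 ± 47.3 against 6.53 ± 2.22 FPKM, limma adjusted p = 7.88e-07), the estrogen-regulated gene Greb1 (24.1 ± 13.9 against 1.404 ± 2.05 FPKM), the hepcidin gene Hamp2 (4161 ± 2651 against 396 ± 249 FPKM) and the complement regulator Susd4 (67.8 ± 26.3 against 14.6 ± 8.76 FPKM). The lowest were in the transporters Slc22a27 (2.43 ± 3.14 against 49.98 ± 11.04 FPKM) and Slc22a29 (0.49 ± 0.891 against 26.6 ± 14.9 FPKM), the receptor Adgrg2 (11.4 ± 7.598 against 151 ± 22.3 FPKM), the thyroxine-binding globulin Serpina7 (40.1 ± 34.9 against 512 ± 130.5 FPKM, log2 change -3.95, SE 0.38), Cyp2c38 (34.9 ± 12.8 against 374 ± 124 FPKM, log2 change -3.42, SE 0.305) and Aqp7 (4.22 ± 6.59 against 36.9 ± 35.5 FPKM). The Aqp7 call ended without sgGFP replicate 1 (limma adjusted p = 0.0523) and in the fit of the 2 groups (0.102). In the library labelled Tbx3 KO replicate 7 Sult1e1 was at 349 FPKM, against 2072 to 3703 in the other 6 and 6.28 to 418 in the controls. Igfbp2 was at 546 there, against 514 to 784 and 70.5 to 202, and Hamp2 was at 391, below the control mean in FPKM though above it on the log2 scale.

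**Figure D5:**
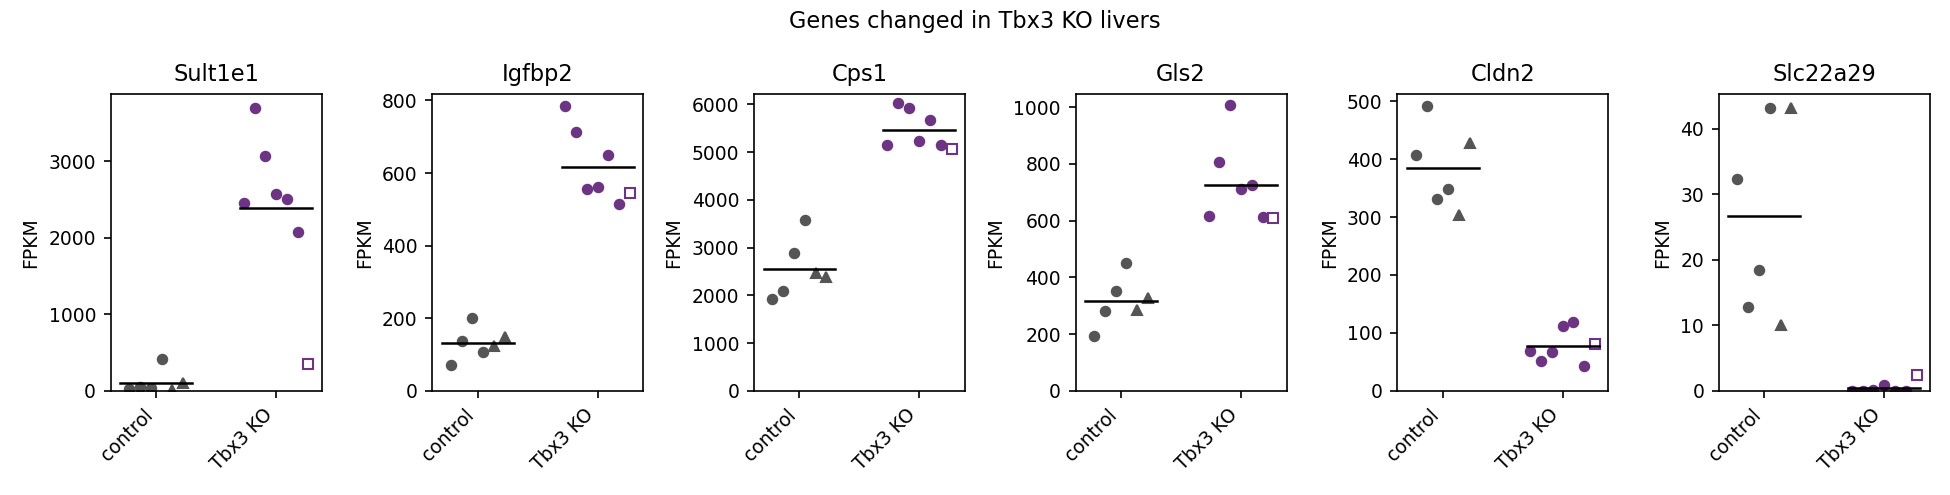
FPKM of Sult1e1, Igfbp2, Cps1, Gls2, Cldn2 and Slc22a29 (vertical axes) in each control and Tbx3 KO liver, with circles for livers, triangles for sgLacZ controls, an open square for the library labelled Tbx3 KO replicate 7 and a black line at each mean. In Sult1e1 that library lay at 349 FPKM, among the controls (6.28 to 418), while in Igfbp2 it lay at 546, with the other 6 Tbx3 KO livers (514 to 784).

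Pericentral genes moved both ways without a list call in Tbx3 KO. Of 27, 2 rose and 3 fell, 4 and 3 adjusted over the list alone (camera adjusted p = 0.894). The tight junction protein Cldn2 fell to 77.2 ± 28.4 from 385 ± 69.9 FPKM (log2 change -2.37, SE 0.17, limma adjusted p = 1.11e-10), and the dicarboxylate transporter Slc13a3 fell (12.6 ± 6.44 against 30.3 ± 5.21 FPKM). The ammonium transporter Rhbg stood at 24.5 ± 6.22 against 10.7 ± 6.61 FPKM (limma adjusted p = 0.0124), a call that ended without sgGFP replicate 1 (0.0541) and in the fit of the 2 groups (0.0985). Genes of xenobiotic metabolism rose in 1 of 28 cases and fell in 5, by either adjustment, without a list call (camera adjusted p = 0.4197), with Cyp3a11 at 623 ± 658 against 3451 ± 569 FPKM. Meg3, an imprinted RNA, stood at 10.9 ± 6.76 against 1.41 ± 0.944 FPKM.

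Of 26 hepatocyte genes 6 rose and 1 fell, 13 and 1 adjusted over the list alone (camera adjusted p = 1.16e-08, and 0.126 with an estimated correlation). Of 22 lipid droplet genes 1 rose and 6 fell, 1 and 10 adjusted over the list alone, with the droplet coat protein Plin4 at 164 ± 43.99 against 457 ± 106 FPKM and Hsd17b13 at 1627 ± 416 against 922 ± 56.7 FPKM (camera adjusted p = 5.84e-05, and 0.169 with an estimated correlation). Among 25 NRF2 targets 4 fell, and 1 was higher and 8 lower adjusted over the list alone, with Gstm3 at 64.1 ± 61.7 against 257 ± 70.2 FPKM (camera adjusted p = 6.47e-06, and 0.307 with an estimated correlation). Female-biased genes rose in 1 of 28 cases and fell in 4, 1 and 5 adjusted over the list alone, with the lipoprotein receptor Vldlr at 4.32 ± 2.34 against 41.3 ± 7.09 FPKM, Cyp2a4 at 10.1 ± 13.7 against 49.2 ± 19.98 FPKM and Cyp3a44 at 2.25 ± 3.44 against 13.1 ± 5.31 FPKM (camera adjusted p = 0.00284, and 0.319 with an estimated correlation). Male-biased genes rose in 3 of 27 cases, 4 adjusted over the list alone, with Cyp2f2 at 1014 ± 177 against 432 ± 147 FPKM (camera adjusted p = 0.000971, and 0.662 with an estimated correlation). Apolipoprotein genes rose in 5 of 29 cases, 6 adjusted over the list alone (camera adjusted p = 0.000137, and 0.126 with an estimated correlation). Genes of oxidative phosphorylation rose in 4 of 27 cases, 6 adjusted over the list alone, and of the unfolded protein response in 2 of 25, 4 adjusted over the list alone (camera adjusted p = 1.08e-08 and 2.47e-05, and 0.307 with an estimated correlation for each).

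Stellate cell genes fell in 3 of 28 cases in Tbx3 KO, 17 adjusted over the list alone, and in 17 over all genes without the library labelled Tbx3 KO replicate 7 (camera adjusted p = 1.49e-09 with all livers, and 0.319 with an estimated correlation). The collagen genes Col1a1 and Col3a1 were above their control means in that library. Col1a1 was at 46.0 FPKM there, 2.86 to 25.2 in the other 6 and 18.5 to 71.0 in the controls, and Col3a1 at 125, 14.0 to 60.2 and 56.5 to 170.4. Macrophage genes had 0 of 26 past the threshold with all livers (camera adjusted p = 0.0201, and 0.838 with an estimated correlation) and 6 lower without that library. The macrophage list call ended without Tbx3 KO replicate 1 or 5 or sgGFP replicate 3 (camera adjusted p up to 0.157) and in the fit of the 2 groups (0.0568). Cholangiocyte genes fell in 1 of 15 cases, 5 adjusted over the list alone (camera adjusted p = 0.00703, and 0.662 with an estimated correlation), a call that ended without sgGFP replicate 1 or 3 (up to 0.133). Bile acid genes rose in 2 of 22 cases and fell in 2 (camera adjusted p = 0.00661, and 0.319 with an estimated correlation), a call that ended without sgGFP replicate 3 (0.0835) and under quantile normalization (0.181). The interferon list had 0 of 28 past the threshold (camera adjusted p = 0.0462, and 0.838 with an estimated correlation), and its call ended without Tbx3 KO replicate 4 or 7, sgGFP replicate 1 or 4 or either sgLacZ liver (up to 0.477) and in 6 of 11 alternatives (up to 0.903).

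In all, limma called 490 genes in Tbx3 KO, 225 higher and 265 lower, of which 50 and 107 changed at least 2-fold. Higher calls made up 45.9% as deposited, 57.6% under median scaling and 49.6% under quantile normalization. The count was 96 in the fit of the 2 groups and 1471 without the library labelled Tbx3 KO replicate 7, of which 487 were among the 490. It was 314, 258 and 299 without Tbx3 KO replicates 2, 3 and 5, and 258 and 295 without sgGFP replicates 1 and 2. List counts moved as well without single livers. The periportal count was 11 to 15 and stayed within 1.5 times, while higher hepatocyte genes numbered 2 (without sgGFP replicate 1) to 10, apolipoprotein genes 1 to 8, oxidative phosphorylation genes 1 to 5, higher bile acid genes 0 to 5, unfolded protein response genes 0 to 4, stellate cell genes 0 to 17 and cholangiocyte genes 0 to 4. Leaving out Tbx3 KO replicate 2 or 3 or sgGFP replicate 1 moved each of the latter counts by over 1.5 times, and every other liver moved some of them.

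Smyd2 KO livers held no gene past the threshold against control. With limma 0 of 19295 genes were called, 1384 had an unadjusted p under 0.05, and the smallest adjusted p was 0.132. The count was 0 in every alternative except sgGFP livers alone as control, with 12, and it was 4 without Smyd2 KO replicate 6, 3 without sgGFP replicate 4 and 1 without sgLacZ replicate 1. The smallest p belonged to the syntaxin Stx4a (171 ± 41.5 against 409 ± 140.2 FPKM, log2 change -1.22, SE 0.23, limma adjusted p = 0.132), the growth factor Vegfb (139 ± 23.4 against 243 ± 65.3 FPKM), Frrs1 (457 ± 121 against 850.1 ± 283 FPKM), the protease inhibitor Serpina1a (1407 ± 210.1 against 988 ± 133 FPKM) and the kinase Map2k2 (613 ± 68.6 against 889.6 ± 65.1 FPKM), with adjusted p of 0.163 for Vegfb, Frrs1 and Serpina1a and 0.188 for Map2k2, each on 1 side of the control mean in 6 of 6 livers.

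Camera called 13 lists in Smyd2 KO, none of which held with an estimated correlation, and no member of any list passed the threshold over all genes. Male-biased genes were higher, 11 of 27 adjusted over the list alone, with a mean log2 change of 1.06 (camera adjusted p = 1.31e-15, and 0.171 with an estimated correlation). Fatty acid synthesis genes were lower, 8 of 20 adjusted over the list alone (mean log2 change -0.496, camera adjusted p = 1.71e-09, and 0.208 with an estimated correlation). Hepatocyte and periportal genes were higher, 5 of 26 and 3 of 23 adjusted over the list alone (camera adjusted p = 1.71e-09 and 5.75e-05, and 0.171 and 0.208 with an estimated correlation). Cholesterol genes (0.000173, and 0.622), female-biased genes (0.000662, and 0.248) and NRF2 targets (0.00128, and 0.622) were lower, and apolipoprotein (0.00273, and 0.208) and acute phase genes (0.00273, and 0.622) higher, by camera adjusted p with the estimated-correlation value last. The calls of oxidative phosphorylation, cholangiocyte, bile acid and stellate genes (camera adjusted p from 0.00516 to 0.0400) ended without 1 of Smyd2 KO replicates 1, 3 or 4 or sgGFP replicates 1 or 3 (up to 0.723), that of stellate genes also in the fit of the 2 groups (0.0573) and that of bile acid genes there and under quantile normalization, that of the apolipoproteins without sgGFP replicate 3 (0.0985), that of acute phase genes without Smyd2 KO replicate 4 (0.0507), and those of cholesterol genes and NRF2 targets with sgGFP livers alone as control (0.0521 and 0.0611).

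The 2 kinds of control guide were compared with each other. Mrpl14 and Rpl36al, ribosomal protein genes of mitochondria and cytosol which were chosen after their values were seen, were higher in sgLacZ than in sgGFP livers, at 109.8 against 37.0 FPKM and 137.8 against 45.1 (log2 changes 1.59 and 1.604, limma adjusted p = 0.0288 for both). No other gene passed, and 1289 had an unadjusted p under 0.05. The count was 0 without sgGFP replicate 1 or either sgLacZ liver and 6 without sgGFP replicate 4.

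The knockouts were also compared directly. By the F test 2791 genes differed among the 5 knockouts. Bcl6 KO stood furthest from the others, with 1125 to 2186 genes different from each other knockout, and female-biased genes were higher in it than in Irs1, Smyd2, Srebf1 and Tbx3 KO by mean log2 differences of 4.70, 4.08, 3.77 and 4.29 (camera adjusted p with an estimated correlation 4.54e-08, 3.18e-09, 2.33e-07 and 3.59e-08). Cholesterol genes were lower in Irs1 KO and Smyd2 KO than in Srebf1 KO by mean log2 differences of -1.295 and -1.14, and 0.81 higher in Srebf1 KO than in Tbx3 KO (camera adjusted p with an estimated correlation 0.00781, 0.00123 and 0.0474). Steatosis genes were lower in Irs1 KO than in Smyd2 KO and Srebf1 KO, by -0.91 and -0.96 (0.00934 and 0.00241 by the same camera test). Periportal genes were lower in Smyd2 KO and Srebf1 KO than in Tbx3 KO, by -0.42 and -0.36 (0.00376 and 0.0474), and higher in Irs1 KO than in Smyd2 KO by 0.34 (0.0388). No other of the 10 pairs passed this test for the cholesterol, steatosis or periportal genes, where the smallest remaining values were 0.163, 0.0825 and 0.119. Smyd2 KO and Srebf1 KO differed in 15 genes, the fewest of the 10 pairs.

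Changes in Irs1 KO and Tbx3 KO overlapped, with 101 genes higher and 154 lower in both, where independent lists of these sizes would share 7.3 and 20.2. In opposite directions 2 and 2 genes were shared (8.6 and 17.1 if independent). Across genes, which are not independent replicates, their log2 changes had r = 0.627, with 0.497 in simulated unchanged groups against the same controls and 0.292 after splitting the controls. The covariance was 0.170, against 0.0591 simulated and 0.0992 with split controls. Irs1 KO and Srebf1 KO shared 18 higher and 20 lower genes (1.2 and 2.7 if independent) and 0 and 1 in opposite directions (1.1 and 2.9). Here r was 0.61, 0.453 in simulated groups and 0.274 with split controls, and the covariance 0.1631, 0.0581 and 0.0922. Bcl6 KO and Irs1 KO shared 97 higher and 163 lower genes (18.5 and 46.8 if independent), and 30 and 29 changed in opposite directions (43.4 and 19.9). Their r was 0.29, 0.454 in simulated groups and 0.073 with split controls, and the covariance 0.1004, 0.0583 and 0.0295.

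Some lists were called the same way against these 6 controls across knockouts, by camera with the preset correlation. In all 5 knockouts hepatocyte, periportal and apolipoprotein genes were higher, and stellate cell and cholangiocyte genes lower. Male-biased genes were called higher in all but Bcl6 KO, but with an estimated correlation only in Irs1 KO. With an estimated correlation the stellate, cholangiocyte and apolipoprotein calls held in none of the 5 (camera adjusted p from 0.174 to 0.843, 0.343 to 0.694 and 0.0521 to 0.208), the hepatocyte call ended in Smyd2 KO and Tbx3 KO, and the periportal call in Bcl6 KO and Smyd2 KO. Of all 34 livers sgGFP replicates 3 and 1 had the lowest hepatocyte list levels (-0.501 and -0.385) and the highest cholangiocyte levels (2.125 and 1.561). Without both livers the Irs1 KO difference was 0.362 (SE 0.05) for hepatocyte and -0.556 (SE 0.152) for cholangiocyte genes, against 0.449 (SE 0.068) and -1.131 (SE 0.398) with all controls.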

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

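The tests of the libraries labelled Srebf1 KO replicate 1 and Tbx3 KO replicate 7, and the comparison of stellate with endothelial genes, were chosen only after the result was seen, and the tests of these 2 libraries replaced earlier forms. For Srebf1 KO replicate 1 an earlier form was undecided and another placed the library between control and knockout. For Tbx3 KO replicate 7 an earlier form used fewer genes, and its shared-state test was divided, and given a margin for the spread of the correlations, after these were seen. The test without sgGFP replicates 1 and 3 and the counts over other splits of the livers were planned.

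A library was singled out where its gap to the nearest liver of its group, divided by the range of the group on the log2 scale, was larger than Dixon's critical value allows. This held in 22 of 296 groups tested, 7.4%, and chance gives about 1 in 20. Of these groups 5 had sgGFP replicate 3 apart, 3 each had sgGFP replicate 4 and Tbx3 KO replicate 7, 2 had Bcl6 KO replicate 5, and 1 each had 9 other libraries.

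In the controls, sgGFP replicate 3 was lowest for Cidea (4.43 FPKM, others 27.4 to 67.8, ratio 0.651), Ghr (763, others 1123 to 1343, ratio 0.684), Cd36 (2237, others 2905 to 3270, ratio 0.688), Aacs (44.1, others 92.4 to 127.9, ratio 0.693) and Fads2 (1127, others 1388 to 1493, ratio 0.74). In sgGFP replicate 4 Lcat was highest (209.5 FPKM, others 125 to 144, ratio 0.727), and Sprr1a (5.99, others 17 to 28.2, ratio 0.662) and Cyp4a31 (7.91, others 29.0 to 46.5, ratio 0.726) lowest. Mir1942 was at 5.98 FPKM in sgLacZ replicate 1 and listed at 0 in the other controls (ratio 1.0), and C8b was lowest in sgLacZ replicate 2 (98.4, others 182 to 217, ratio 0.776). The implied depth of sgGFP replicate 1, 2300000 reads, was the lowest among the controls (ratio 0.647).

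Among the Bcl6 KO livers, replicate 5 was highest for Cidea (23.4 FPKM, others 0 to 0.988, ratio 0.785) and for Tinag (2.22, others at 0, ratio 1.0). Smyd2 was highest in replicate 3 (146.9, others 79.3 to 92.1, ratio 0.757) and Clec4g lowest in replicate 4 (77.5, others 108 to 119.9, ratio 0.767). In Irs1 KO replicate 1 Mmp12 was lowest (0.534 FPKM, others 9.39 to 13.7, ratio 0.848), and in Srebf1 KO replicate 5 Siglecf was at 0.438 and at 0 in the other 4 (ratio 1.0). In Tbx3 KO replicate 3 Adgrg2 was listed at 0 (others 5.32 to 22.9, ratio 0.581). Tbx3 KO replicate 7 was lowest for Sult1e1 (349 FPKM, others 2072 to 3703, ratio 0.754) and AW549542 (24.6, others 84.7 to 166, ratio 0.645) and highest for Slc13a3 (26.7, others 8.08 to 12.4, ratio 0.65). Srebf1 was highest in the library labelled Srebf1 KO replicate 1 (1908 FPKM, others 498.8 to 631.7, ratio 0.824).

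Srebf1 KO replicate 1 held control-level Srebf1 mRNA. Its position was measured on genes called for 1 knockout alone, from 0 (control mean) to 1 (knockout mean). On the 67 Irs1 KO genes it lay at 0.466 (controls -0.083 to 0.113, other Srebf1 KO 0.015 to 0.132, Irs1 KO 0.685 to 0.94). This cannot decide against a mislabelled control, since Smyd2 KO livers, with 0 genes called against control, reached 0.539. On the genes of Bcl6 KO and Tbx3 KO the library lay at -0.058 and 0.155, outside those knockouts (0.736 to 1.155 and 0.777 to 1.027). A mislabelled Smyd2 KO liver also stays open, though Smyd2 mRNA was 179.5 FPKM here and 61.7 to 121.4 in Smyd2 KO. Partial loss of Srebf1 also stays open. On the 16 Srebf1 KO genes the library lay at 0.158, within controls (-0.124 to 0.25) and below the other 4 (0.697 to 1.048). On the 81 genes called for Srebf1 KO without it, it lay at 0.545, above other groups (up to 0.412), below the other 4 (0.603 to 0.877).

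The library labelled Tbx3 KO replicate 7 lay at 0.071 on the 1465 genes called for Tbx3 KO without it, among the controls (-0.002 to 0.412). On the 36 genes called for Tbx3 KO alone it lay at 0.56, above the controls (-0.082 to 0.171) and every liver of another knockout (up to 0.447), which argues against a control liver under the wrong label. A liver state shared with sgGFP replicates 1 and 3 and Smyd2 KO replicate 6 stays open: its deviations from its group mean correlated across genes with theirs at r = 0.045, 0.251 and 0.325, and with the other 24 livers outside its group at -0.272 to 0.215 (SD 0.11), the highest in Bcl6 KO replicate 3. The last 2 of the 3 livers were picked from these correlations, and for sgGFP replicate 1 their spread leaves the question undecided. Tbx3 KO replicate 7, sgGFP replicate 1, sgGFP replicate 3 and Smyd2 KO replicate 6 had list levels of 1.059, 1.093, 1.381 and 1.382 for stellate cells, 1.55, 0.586, 1.154 and 1.225 for macrophages, 1.267, 1.561, 2.125 and 1.522 for cholangiocytes and 1.538, 0.005, 1.624 and 0.912 for neutrophils, against a mean of 0 over the 34 livers, and no biological explanation was tested.

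Stellate cell and macrophage genes were lower in Irs1 KO by mean log2 changes of -1.224 (SE 0.238) and -1.099 (SE 0.228), each with a two-sided exact permutation p = 0.002165, the smallest that 5 against 6 livers allow, though against other genes neither list call held with an estimated correlation (camera adjusted p = 0.174 and 0.258). Without sgGFP replicates 1 and 3, which had high levels, the changes were -0.881 (SE 0.098) and -0.84 (SE 0.152), which argues against these 2 controls as the whole cause. An equal drop of all cell types but hepatocytes was argued against. Stellate minus endothelial genes differed by -1.078 (SE 0.247, exact permutation p = 0.004329), lower in 5 of 5 Irs1 KO livers. Unequal drops stay open, with T, B and NK cell (-0.302) and neutrophil genes (-0.691) lower in 5 of 5. So does an effect of the knockout, and cell number and transcripts per cell were not tested.

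Counts of called genes were set against 100 splits of the same livers into groups of the same sizes, the real split included. Only 1 of the 100, the real split, gave as many genes in Bcl6 KO (1185, the highest other 681) and in Irs1 KO (2094 and 937). The same held in Srebf1 KO (73 and 22), in Tbx3 KO (490 and 23) and among the 5 knockouts (1 regrouping, 2791 and 8). This argues against chance as the source of these counts. It does not exclude chance, since 100 of 462 possible splits were drawn, and 100 of 1716 for Tbx3 KO. In Smyd2 KO the real split called 0 genes and the highest other 191. Any split gives at least 0, so 100 of 100 did and the count decides nothing about chance there. The median of the other splits was 0, and 84 of them called 0 genes. Why 1 split called 191 was not tested.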

How the results depend on the processing

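The fit without the 3 libraries lowest on the first principal component (sgGFP replicate 3, Tbx3 KO replicate 7 and Smyd2 KO replicate 6) was chosen only after the result was seen, and all other alternatives were planned. No named gene that had passed changed direction. Under median scaling the balance of higher and lower calls turned, to 671 and 374 in Bcl6 KO, 1011 and 937 in Irs1 KO and 289 and 213 in Tbx3 KO. Of 259 genes that the naming rule covers and that were called, 170 kept their call in every alternative and without any 1 liver wherever they were tested, 163 of them tested each time (50 of 71 in Bcl6 KO, 91 of 105 in Irs1 KO, 2 of 25 in Srebf1 KO and 27 of 58 in Tbx3 KO), as did 25 of 30 that were not called. Of 84 called lists 63 did (12 of 12, 20 of 24, 5 of 13 in Smyd2 KO, 16 of 21 and 10 of 14), 62 tested each time. The filter on low values left the others untested in some fits, among them A1bg, Sult2a1 and Cyp3a41b without any 1 Bcl6 KO liver, and the adipocyte list in Srebf1 KO under the stricter filter. Counts moved by over 1.5 times in these cases, whose cause was not tested unless stated. In a fit of the compared groups alone, which has fewer livers to estimate the spread, Bcl6 KO had 750 genes, Srebf1 KO 10, Tbx3 KO 96 and sgLacZ against sgGFP 8. With sgGFP livers alone as control Smyd2 KO had 12 and Srebf1 KO 152. Without a filter on low values sgLacZ against sgGFP had 12. Without the 3 libraries Tbx3 KO had 1191. Single livers left out gave 743 to 1204 (without sgGFP replicate 4) genes in Bcl6 KO and 1424 to 2185 in Irs1 KO. They gave 0 to 4 in Smyd2 KO, 14 to 110 in Srebf1 KO and 258 to 1471 in Tbx3 KO. Among the 5 knockouts they gave 2226 to 3535, and between the controls 0 to 6. With 1 sgLacZ liver left, that liver is assumed to vary like the other groups. The replicate numbers do not pair the livers: 83 pairs of the same number had a mean correlation of deviations of -0.005 (-0.163 to 0.162, 2 over 0.1), and 6 of 34 livers were closest to their own number. With the number as a block Srebf1 KO had 133 genes, Tbx3 KO 1931 and sgLacZ against sgGFP 1, and the other counts stayed within 1.5 times. Replicate 7 exists only in Tbx3 KO, so the block removes that library from the comparison. At 2110000 to 3130000 counted reads per library, genes of a few FPKM rest on few reads, and a change in them may be missed or overstated: with a pseudocount of 0.1 the log2 change of H19 in Srebf1 KO was -4.28 (limma adjusted p = 0.0734), against -3.48 (0.0335) with 1, and its adjusted p was up to 0.113 without 1 liver.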

Other observations

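The tests of female-biased genes outside the large enzyme and transporter families and of sex chromosome genes were chosen only after the result was seen, as were the genes Xist, Ddx3y, Cux2, Hao2, Prom1 and Ntrk2. The list tests were planned. Y-linked transcripts were present in all livers, and Ddx3y lay at 237.2 to 273.9 FPKM in Bcl6 KO and 177.7 to 281.9 in the other livers. Xist, expressed from the inactive X chromosome of females, lay at 0.308 to 1.95 FPKM in Bcl6 KO and 0 to 2.26 in the others. Of 9 female-biased genes outside the Cyp, Sult, Fmo, Acot and Slc22 families, 4 rose in Bcl6 KO: A1bg, the transcription factor Cux2 (log2 change 6.76, SE 0.53), Prom1 (2.49, SE 0.56) and the hydroxyacid oxidase Hao2 (1.53, SE 0.45), with limma adjusted p of 1.84e-29, 2.11e-11, 0.00425 and 0.0374. Ntrk2 fell by 1.67 (SE 0.36, limma adjusted p = 0.00264).

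Livers also differed within groups. The first principal component held 13.9% of the variance and was lowest in sgGFP replicate 3 (-74.6), Tbx3 KO replicate 7 (-59.8), Smyd2 KO replicate 6 (-56.5), Bcl6 KO replicate 3 (-52.3) and sgGFP replicate 1 (-48.7). The second held 8.7% and placed the Bcl6 KO livers at 43.1 to 79.3. Adipocyte genes lay at 0.78 to 1.07 in Srebf1 KO and -0.61 to 0.60 in the controls, and were higher in Srebf1 KO than in Bcl6 KO and Tbx3 KO (mean log2 differences -1.53 for Bcl6 minus Srebf1 and 1.44 for Srebf1 minus Tbx3, camera adjusted p with an estimated correlation 0.0234 and 0.0132). The differences of Irs1 KO and Smyd2 KO from Srebf1 KO, -1.23 and -0.49, did not pass (0.0589 and 0.301), and 5 of 6 Smyd2 KO livers lay at 0.385 to 0.892. The list of pancreatic acinar genes, a check for neighbouring tissue, had 2 tested members, too few to test.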
